A study of Mus musculus with 6 samples.

How the data were processed

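Whole lung RNA of 6 libraries was used, 3 from untreated female C57BL/6N mice and 3 from mice examined 100 days after a single 20 Gy dose of 9 MeV electrons. Per the labels' protocols, total RNA was extracted with TRIzol, polyA libraries were made with a dual-mode mRNA kit and sequencing was run on a DNBSEQ-T7. The submitters' processing notes name fastp, STAR 2.7.6a, DESeq2 and the GRCm39 build, with no role or order. The step that made the deposited tables, the library strand setting and the annotation are not given in the sources used here. Per the file headers, each library has a table with the location, coverage, FPKM and TPM of each gene, in the column layout of a StringTie gene abundance table.

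The values analysed are the FPKM as deposited by the authors, that is a level scaled for transcript length and for the mapped fragments of the library, as the file headers name it. Each table holds 40842 reference genes and, beside them, 22644 to 24988 genes assembled from that library without a name. The deposited TPM column was not used, because its values over the reference and the assembled genes together sum to about 2 times what a TPM column sums to. The deposited coverage (signal per base of a gene) was used only to estimate depth: the ratio of FPKM to coverage is a constant of the library for genes with a single transcript, and it implies 6.28, 6.77 and 5.89 Gb of aligned sequence in control 1 to 3 and 5.82, 10.4 and 5.11 Gb in irradiated 1 to 3. Without counts no counting interval can be given, and low values carry more counting error in the shallower libraries. A few reference genes had several entries in a table, and these were summed. Genes were taken by symbol. Each sequence of the files was given the chromosome that most of its genes have, by symbol, in a table of RefSeq genes of another build. That table was used for names and chromosome numbers alone. Coordinates are those of the files (GRCm39, counted from 1). Exons and UTRs were not analysed here.

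The design fixed before the data were examined named a count model as the main test and limma on log values where the files held no counts. As the files hold FPKM, limma 3.58.1 in R 4.3.3 was used with a mean-variance trend and robust variance estimates on log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 13908 in all, with the group as the model's only term. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 was called. A log2 change is irradiated minus control on the log2(FPKM + 1) scale, which understates the change of genes near 1 FPKM or below. It is given with its standard error, and FPKM are given as mean ± SD over 3 libraries per group unless stated.

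A set of 40 gene lists of lung cell types, radiation and immune responses, and possible contaminants was also fixed before the data were examined. Of their 555 members, 542 were matched to a gene in the files, 3 of them through another symbol. Lists with at least 3 tested members, 36 in all, were tested with camera (limma) at a preset inter-gene correlation of 0.01, and the p-values were adjusted over the lists. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in a direction, were run beside it. Gene counts within a list are given over all genes tested and adjusted over the list alone.

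The genes named in the text follow a rule that was also fixed beforehand. It takes up to 15 genes per direction with the largest change among called genes with a mean of at least 2 CPM and with groups that do not overlap, up to 4 members with the smallest p per list, the 5 genes with the smallest p per direction, and 10 genes chosen for the study's subject. The CPM minimum was applied to FPKM. Predicted and clone-based names were left out, and some genes that the rule takes are not reported here. Genes named outside this rule are stated to have been chosen after their values were seen.

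The procedure was tested on simulated data before use. In 20 simulations of 3 against 3 libraries with the levels and spread of the 13908 genes, 200 genes with a mean log2(FPKM + 1) above 2 were changed. Noise was drawn independently for each gene. Recovery of lower genes was therefore not tested, and the share of false calls does not cover variation that genes share. The fit recovered 33.6% of genes changed by 1.5-fold, 71.3% of those changed by 2-fold and 93.6% of those changed by 4-fold, and 5.03% of the calls were false. Other scalings, filters, pseudocounts, variance estimates, a threshold on fold size, the replicate number as a block and leaving out each library in turn were tried as alternatives. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.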

Results

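Gene expression in whole lung was measured by polyA RNA sequencing in 3 untreated female C57BL/6N mouse libraries (control 1 to 3) and in 3 libraries (irradiated 1 to 3) taken 100 days after a single 20 Gy dose of 9 MeV electrons. The labels do not name the part of the body that was exposed. The title of the series is about γδ T cells that make IL-17 (γδ17 cells) and neutrophils in radiation pneumonitis, the inflammation of the lung that follows its irradiation, and the comparison asks how lung RNA differs between exposed and untreated mice at this late time. The depth implied by the deposited values was 5.11 to 10.4 Gb per library, with irradiated 2 the deepest. Between 13467 and 14050 genes per library reached 1 FPKM. The labels do not say that the libraries of a group come from separate mice, so p-values measure the spread between these libraries, which may be technical.

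In irradiated lung, among the genes past the threshold, Saa3, Lcn2 and Steap4 rose most and Aplnr fell most on the log2(FPKM + 1) scale, which understates the change of genes at low levels. By the ratio of group means Serpina3m and Psrc1, both at low levels, rose more than Lcn2 and Steap4. Saa3, an acute-phase serum amyloid, rose from 1.31 ± 0.638 to 19.9 ± 9.38 FPKM (log2 change 3.11 ± 0.35), and Lcn2, an iron-binding protein of the innate immune response, rose from 84.7 ± 19.8 to 374 ± 75.1 FPKM (2.13 ± 0.21). Steap4, a metalloreductase induced in inflammation, rose from 4.37 ± 1.04 to 21.1 ± 2.83 FPKM (2.05 ± 0.16). Aplnr, the receptor for the peptide apelin, which marks general capillary endothelium in lung, fell from 15.1 ± 1.44 to 2.46 ± 1.03 FPKM (−2.25 ± 0.21). In all, 25 of 13908 genes passed an adjusted p of 0.05 with limma, 9 of them higher and 16 lower, and their adjusted p lay between 0.0298 and 0.0475.

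The other 6 genes that rose were Serpina3m, Psrc1, Akr1c14, Arg2, Adamts15 and Trp53inp1, with log2 changes from 1.26 to 1.68. Psrc1 and Trp53inp1 are p53 targets, Akr1c14 is a hydroxysteroid dehydrogenase, Arg2 is the mitochondrial arginase, and Adamts15 is a secreted protease. Akr1c14 and Serpina3m have close family members that could share their reads. Serpina3m had a low level (0.455 ± 0.204 against 3.64 ± 0.376 FPKM). Its neighbour Serpina3n, chosen after its values were seen, was at 25.9 ± 3.56 against 88.2 ± 39.9 FPKM (limma adjusted p = 0.0793). Arg2 overlaps Vti1b on the opposite strand, whose own log2 change was −0.22.

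Among the genes that fell after Aplnr, the cadherin Cdh16 (−1.41 ± 0.14), the cystatin Cst8 (−1.32 ± 0.16), neuritin Nrn1 (−1.30 ± 0.10), the atypical chemokine receptor Ackr4 (−1.27 ± 0.13) and the complex IV assembly factor Cox20 (−1.25 ± 0.13) had the largest changes on the log2(FPKM + 1) scale. By the ratio of group means Fam178b and Krt23 fell further than Cox20. Nrn1 fell from 12.5 ± 1.21 to 4.47 ± 0.276 FPKM, and Cox20 fell from 40.3 ± 4.67 to 16.3 ± 2.05 FPKM. Cox20 overlaps Hnrnpu, which had a log2 change of −0.32, and Ackr4 lies within Acad11, which had a log2 change of 0.13. Without a stated strand setting their reads cannot be told apart from those of the overlapping gene. The same holds for Slc7a10, Clec9a, Nr1d1, Dbp, Ighg1 and Ighg2c, named further on, which overlap another expressed gene. Further genes that fell were Fam178b, Krt23, Myct1, Ddah2, Scn7a, AU021092, Dpysl2, Dpp4 and Gpt, with log2 changes from −1.19 to −0.70. Lgi3 (−0.69), named although it falls outside the naming rule, fell as well. Myct1 is expressed in endothelium, Ddah2 is an enzyme family member linked to nitric oxide control, Scn7a is a sodium channel of lung fibroblasts, and Dpp4 is a surface peptidase.

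These genes lie, in GRCm39 coordinates from the files, at chromosome 7, 46361422 to 46365100 (Saa3), chromosome 2, 32274649 to 32277751 (Lcn2), chromosome 5, 8010472 to 8032213 (Steap4), chromosome 2, 84966704 to 84970267 (Aplnr), chromosome 13, 36909596 to 36918451 (Nrn1) and chromosome 1, 178146379 to 178150258 (Cox20). Each value is for the whole gene.

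The number of calls depended on single libraries. With limma no gene passed without control 1 or without control 3 (0 genes, with 1905 and 1650 at an unadjusted p under 0.05, against 2466 with all 6), 1 passed without control 2 and 3 without irradiated 2, while 100 passed without irradiated 1 and 116 without irradiated 3. Of the 25 genes called with all 6 libraries, 1 passed without control 2 and 0 without irradiated 2. Without irradiated 1, 21 of the 25 passed, and without irradiated 3, 24 did. Without control 2 and irradiated 2, the libraries farthest apart on the first principal component, 9 genes passed, 9 of them higher, and 2 of these were among the 25. The split of higher against lower genes was 9 to 16 as deposited, and 8 to 6 when FPKM were rescaled to a common sum. The common sum lay above the libraries' own sums (2.98e5 to 3.51e5), so the 1 added before the log weighed less as well. Lower genes stayed in the majority with median-ratio scaling (5 to 7), with upper-quartile scaling (9 to 18) and without the 20 most abundant genes (11 to 22).

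**Figure D1:**
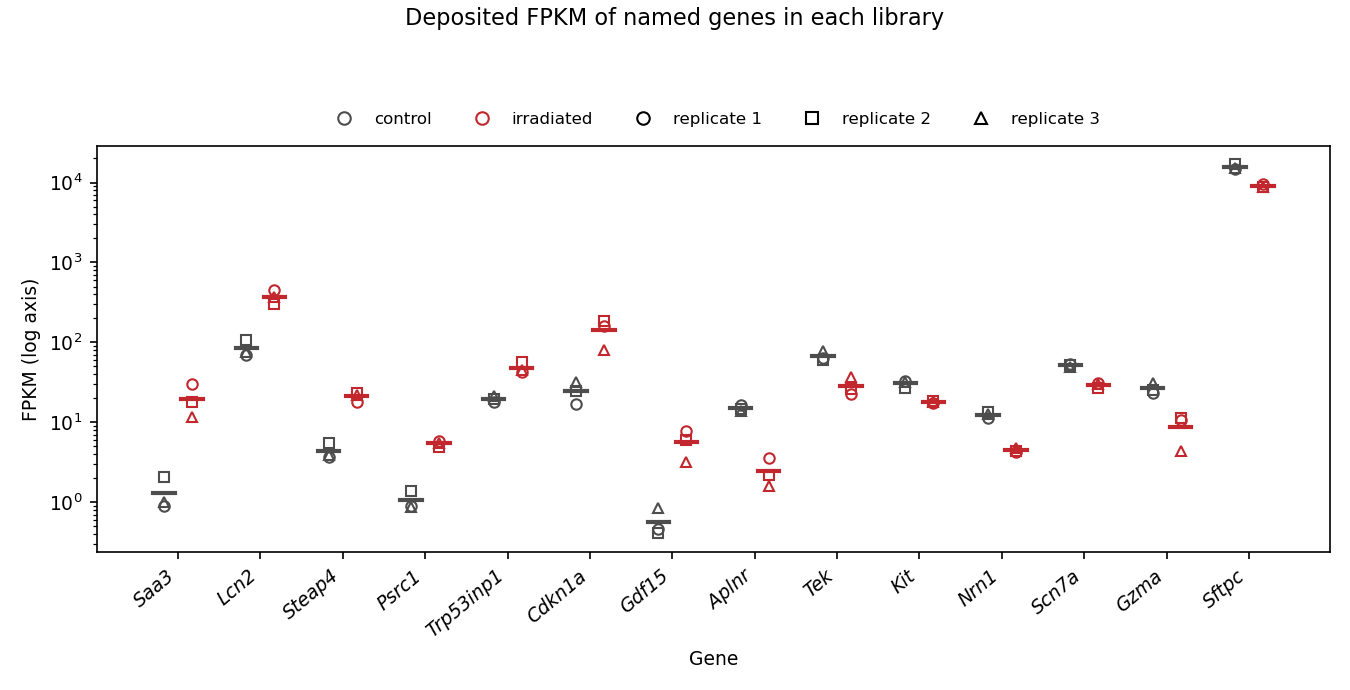
FPKM of 14 named genes in each library on a log axis, with controls in grey, irradiated libraries in red, a marker shape per replicate number and a bar at the group mean. The 3 irradiated libraries lie above the 3 controls for Saa3 to Gdf15 and below them for Aplnr to Sftpc; Cdkn1a, Gdf15, Tek, Kit, Gzma and Sftpc did not pass the adjusted p of 0.05 over all genes.

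Target genes of p53, the transcription factor activated by DNA damage, were higher as a group. Of 20 genes tested, 18 had positive changes, with a median log2 change of 0.71 (camera adjusted p = 8.38e-14; adjusted p = 0.178 with an estimated correlation). Over all genes 2 passed, Psrc1 (1.05 ± 0.296 to 5.48 ± 0.472 FPKM) and Trp53inp1 (19.4 ± 1.63 to 48.3 ± 7.66 FPKM), and 15 passed when adjusted over the list alone. These 15 included Gdf15, a stress cytokine (0.570 ± 0.234 against 5.69 ± 2.38 FPKM), Ccng1, a cyclin induced by p53 (28.0 ± 3.13 against 53.5 ± 8.11 FPKM), and Cdkn1a, the cell cycle inhibitor p21 (24.5 ± 7.33 against 142 ± 54.5 FPKM; log2 change 2.45 ± 0.35, limma adjusted p = 0.0624 over all genes). Cdkn1a lies at chromosome 17, 29309953 to 29319696. This was the only list that passed fry (adjusted p = 0.0143), and its camera call at the preset correlation held without each of the 6 libraries in turn.

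The list of senescence and secretory phenotype genes, which shares Cdkn1a and Gdf15 with the p53 list, was called higher (14 tested, median 0.25, camera adjusted p = 0.0453; adjusted p = 0.816 with an estimated correlation). No member passed over all genes, and adjusted over the list alone Gdf15 and Cdkn1a were higher and Igfbp3, a binding protein of insulin-like growth factors, was lower (35.5 ± 6.83 against 19.1 ± 2.43 FPKM). Its call ended without control 1 (adjusted p = 0.209), without control 2 (0.0898) or without irradiated 1 (0.403).

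Transcripts that mark γδ17 cells were higher as a list (13 tested, 10 with positive changes, median 0.47, camera adjusted p = 0.00291; adjusted p = 0.70 with an estimated correlation). No member passed over all genes, and 4 passed when adjusted over the list alone. These were the γδ receptor segments Trgv6 (0.505 ± 0.114 against 1.51 ± 0.108 FPKM) and Trdv4 (1.21 ± 0.0911 against 3.41 ± 0.970 FPKM), the scavenger receptor Cd163l1 (1.37 ± 0.159 against 4.10 ± 1.46 FPKM) and the δ chain constant region Trdc (2.04 ± 0.0794 against 3.55 ± 0.645 FPKM). These 4 genes lie near the level of the filter, and with a minimum of 5 FPKM the list was not called (adjusted p = 0.712). The cytokine genes were below the filter and were not tested. Il17a was listed at 0, 0 and 0.0800 FPKM in control 1 to 3 and at 0.182, 0.10 and 0.273 FPKM in irradiated 1 to 3, and Il17f at 0.0436, 0 and 0.0218 against 0.0408, 0.0353 and 0.444 FPKM.

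Genes of the IL-17 response, a list that also holds the receptor subunits Il17ra and Il17rc and the adaptor Traf3ip2, were higher (11 tested, 9 with positive changes, median 0.62, camera adjusted p = 0.000195; adjusted p = 0.418 with an estimated correlation). Saa3 and Lcn2 were its 2 members that passed over all genes, both higher. Adjusted over the list alone these 2 were higher and Il17rc was lower (11.7 ± 0.453 against 9.50 ± 0.0515 FPKM), and Tnfaip3, a brake on NF-κB signalling, did not pass (5.12 ± 0.823 against 7.45 ± 1.47 FPKM). Cxcl5, a neutrophil chemoattractant, was below the filter at 0.174, 0.224 and 0.0570 FPKM in the controls and 0.658, 0.90 and 0.443 FPKM in the irradiated libraries.

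Neutrophil markers had a median log2 change of 1.96, the largest of the 36 lists (18 tested, 17 with positive changes, camera adjusted p = 1.04e-05; adjusted p = 0.70 with an estimated correlation), and no member passed over all genes or adjusted over the list alone. The spread between libraries was wide: relative to the control mean the median over the list was −0.22, −0.57 and 0.91 in control 1 to 3 and 0.24, 3.12 and 1.87 in irradiated 1 to 3. S100a8 and S100a9, which form the calprotectin of neutrophils, were at 95.1 ± 91.2 against 871 ± 1026 FPKM and at 115 ± 104 against 899 ± 941 FPKM. Irradiated 2, the library with the highest neutrophil values, also had the highest red cell transcripts, with a list median of 2.12 against −0.03 and 0.07 in irradiated 1 and 3. The red cell list was called higher (7 tested, median 0.76, camera adjusted p = 0.0340; adjusted p = 0.833 with an estimated correlation), and this call ended without irradiated 2 (adjusted p = 0.953), without control 1 (0.127) or without control 2 (0.0837).

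Markers of monocytes and interstitial macrophages were higher as a list (16 tested, 15 with positive changes, median 0.38, camera adjusted p = 8.24e-05; adjusted p = 0.625 with an estimated correlation). Relative to the control mean the list median was 0.70 and 0.32 in irradiated 1 and 3, while irradiated 2 (0.0019) lay within the range of the controls (−0.05 to 0.07). None passed over all genes and 5 did when adjusted over the list alone, among them Lyve1, a hyaluronan receptor (88.2 ± 16.1 against 191 ± 26.8 FPKM), Gpnmb, a glycoprotein of lipid-laden macrophages (2.89 ± 0.263 against 5.19 ± 1.26 FPKM), and the chemokine receptor Ccr2 (10.1 ± 0.540 against 16.6 ± 4.27 FPKM). Lyve1 is also a marker of lymphatic endothelium. Alveolar macrophage markers went both ways and were not called as a list (16 tested, camera adjusted p = 0.828). Adjusted over the list alone, Chil3 and Mrc1 were higher (159 ± 28.0 against 312 ± 94.5 FPKM, and 9.94 ± 0.603 against 15.6 ± 3.63 FPKM), while Krt79 and the scavenger receptor Marco were lower (6.85 ± 2.57 against 2.38 ± 1.23 FPKM, and 6.56 ± 1.71 against 1.79 ± 1.94 FPKM).

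Natural killer cell markers were lower in irradiated lung. All 11 tested members had negative changes, with a median of −0.63 (camera adjusted p = 8.25e-07; adjusted p = 0.563 with an estimated correlation), and in 10 of the 11 the 3 irradiated libraries lay below the 3 controls. None passed over all genes and 9 passed when adjusted over the list alone. Gzma, a granule protease, was at 26.6 ± 3.90 against 8.87 ± 3.95 FPKM, Gzmb at 3.80 ± 0.556 against 1.73 ± 0.523 FPKM, and the receptor gene Ncr1 at 3.18 ± 0.163 against 1.55 ± 0.469 FPKM. Klra8 belongs to a family of near-identical receptors and is uncertain (3.58 ± 0.652 against 1.32 ± 0.424 FPKM). Markers of αβ T cells were called higher with a small median of 0.19 (15 tested, camera adjusted p = 0.0342; adjusted p = 0.934 with an estimated correlation), with no member past the threshold over all genes or over the list alone. That call ended without control 1 (adjusted p = 0.148), without irradiated 1 (0.107) or without irradiated 3 (0.404).

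Capillary and pan-endothelial markers were lower as a list (15 tested, 12 with negative changes, median −0.46, camera adjusted p = 0.000235; adjusted p = 0.644 with an estimated correlation). Aplnr passed over all genes, and 6 genes passed when adjusted over the list alone. Among these, Tek, the angiopoietin receptor, was at 67.3 ± 9.44 against 28.8 ± 7.68 FPKM, Kit, a receptor of general capillary cells and mast cells, at 30.7 ± 3.32 against 17.9 ± 0.710 FPKM, and Tie1, an endothelial receptor kinase, at 63.0 ± 7.42 against 43.6 ± 4.99 FPKM. Markers of aerocytes, the capillary cells of gas exchange, were called higher with a median of 0.18 (10 tested, camera adjusted p = 0.0232; adjusted p = 0.563 with an estimated correlation), with no member past the threshold over all genes or over the list alone. This call ended without control 2 (adjusted p = 0.0898), without irradiated 1 (0.0605) or without irradiated 2 (0.0686).

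Alveolar type 2 cell markers were lower as a list (15 tested, 12 with negative changes, median −0.29, camera adjusted p = 0.0136; adjusted p = 0.816 with an estimated correlation). None passed over all genes. Adjusted over the list alone, Sftpc, the gene of surfactant protein C (15497 ± 1163 against 9048 ± 469 FPKM), and Lamp3, a lamellar body protein (142 ± 3.85 against 99.0 ± 15.9 FPKM), were lower. Alveolar type 1 markers were not called as a list (15 tested, camera adjusted p = 0.892), and Aqp5, a water channel, was the 1 member lower when adjusted over the list alone (151 ± 6.70 against 104 ± 4.84 FPKM).

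Alveolar fibroblast markers were lower as a list (12 tested, 10 with negative changes, median −0.23, camera adjusted p = 0.0232; adjusted p = 0.625 with an estimated correlation). Scn7a passed over all genes (51.8 ± 2.29 to 29.7 ± 2.14 FPKM), and adjusted over the list alone 4 passed, adding the amino acid transporter Slc7a10, the transcription factor Tcf21 and the ligand Wnt2. The call ended without control 3 (adjusted p = 0.0781) and with a minimum of 5 FPKM (0.0888). Mesothelial markers, of the lung's outer lining, were lower (6 of 6 with negative changes, median −0.88, camera adjusted p = 0.00299; adjusted p = 0.70 with an estimated correlation). None passed over all genes, and Lrrn4, Upk3b and Msln were lower when adjusted over the list alone. Their median was highest in control 2 (0.47), which also had the highest cardiac and adipose transcripts, and lowest in irradiated 2 (−1.27).

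**Figure D2:**
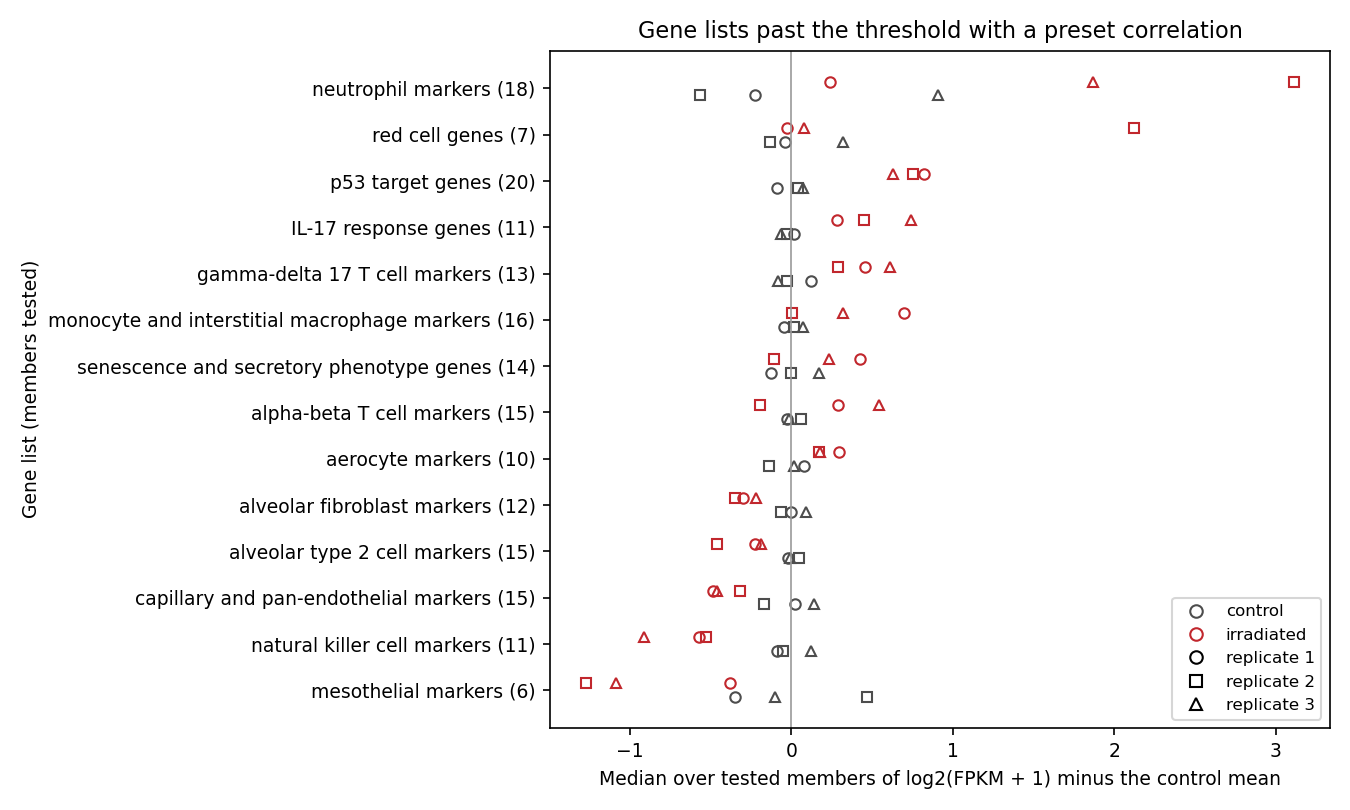
Median over the tested members of each of the 14 called gene lists of log2(FPKM + 1) minus the control mean, per library, with controls in grey, irradiated libraries in red and a marker shape per replicate number. The irradiated libraries lie apart from the controls for the p53, γδ17, IL-17 response, natural killer, alveolar type 2, endothelial, aerocyte, alveolar fibroblast and mesothelial lists. The groups overlap for the senescence, monocyte, αβ T, neutrophil and red cell lists, and the last 2 spread widely, up to 3.12 and 2.12 in irradiated 2.

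Genes of extracellular matrix and fibroblast activation were not called as a list (21 tested, camera adjusted p = 0.410), and Col1a1, the main fibrillar collagen chain, was at 30.5 ± 4.39 against 27.7 ± 22.9 FPKM. Adjusted over the list alone, Lox, an enzyme that crosslinks collagen, was higher (7.36 ± 2.41 against 25.6 ± 7.50 FPKM) and Cthrc1, a secreted protein of activated fibroblasts, was lower (3.19 ± 0.274 against 1.40 ± 0.398 FPKM). The median of this list was 0.74 in irradiated 1 and −0.37 and −0.34 in irradiated 2 and 3, and it was called lower without irradiated 1 (adjusted p = 0.0421) and higher without irradiated 3 (0.00335).

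Of the other lists, B cell markers came closest to the threshold, with 12 of 12 members at negative changes (median −0.34, camera adjusted p = 0.0606), and they were called lower without control 3 (adjusted p = 0.00713) or without irradiated 3 (0.00230). Genes of MHC class II and the interferon-γ response (13 tested, adjusted p = 0.0853) were called lower without irradiated 1 (adjusted p = 0.00202), and Irf1, Gbp2 and Gbp4 were lower when adjusted over the list alone. Dendritic cell markers (10 tested, adjusted p = 0.0871) held Ccl17 and Flt3 higher and Clec9a lower when adjusted over the list alone, and were called higher without irradiated 2 (adjusted p = 0.00990). Complement genes (14 tested, adjusted p = 0.160) held Cfp higher, and were called higher without irradiated 2 (adjusted p = 0.00990) or irradiated 3 (0.0397). Cell cycle genes (25 tested, adjusted p = 0.260) had no member past the threshold and were called higher without irradiated 3 (adjusted p = 0.000409).

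Plasma cell and immunoglobulin genes (14 tested, adjusted p = 0.262), club and secretory cell markers (15 tested, adjusted p = 0.547) and immediate early genes (12 tested, adjusted p = 0.547) were not called. The first of these was called higher without control 2 (adjusted p = 0.00698) or irradiated 2 (0.0162), the second without control 2 (0.0108), and the immediate early genes without control 3 (0.00433). Scgb1a1, the secretoglobin of club cells and the most abundant of these transcripts, was at 37615 ± 6611 against 21418 ± 5195 FPKM (limma adjusted p = 0.164), and Gsta3 was the 1 club cell gene higher when adjusted over the list alone (86.5 ± 2.21 against 128 ± 2.74 FPKM). Ciliated cell markers (15 tested) and circadian clock genes (13 tested) had an adjusted p of 0.561. In the clock list Cry1 and Per2 were higher, and Nr1d1 and Dbp lower, when adjusted over the list alone. Type I interferon response genes (24 tested, adjusted p = 0.828) were called higher without irradiated 3 (adjusted p = 0.0105).

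An adjusted p of 0.828 was also given for lymphoid aggregate genes (7 tested, Ccl21a lower when adjusted over the list alone), mast cell and type 2 genes (4), transitional alveolar epithelium (13), adventitial fibroblasts (11, with Dpp4 lower over all genes), smooth muscle and pericytes (12, Lamc3 higher when adjusted over the list alone), cholesterol synthesis (12), cardiac muscle (9) and adipose genes (5). Median, mean and test differed in sign for the matrix, alveolar macrophage, alveolar type 1, lymphoid aggregate, cholesterol and adipose lists, whose medians lay between −0.04 and 0.04. The lists of skeletal muscle, thymocyte, sex-linked and mitochondrially encoded genes had fewer than 3 tested members and were not tested. Xist was at 23.4 to 33.8 FPKM in all 6 libraries, and the Y-linked Ddx3y, Uty, Kdm5d and Eif2s3y were at 0.00196 FPKM or below.

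The libraries also differed within each group. The first principal component of log2(FPKM + 1) held 36.3% of the variance, with control 2 at −33.3 and irradiated 2 at 39.8 as its ends. Cardiac muscle genes had a list median of 1.82 in control 2 and −2.46 in irradiated 2 relative to the control mean, and adipose genes 1.90 and −1.55. The labels give no batch or date. Between the groups, Scgb1a1 held 9.65 to 13.3% of the summed FPKM of reference genes in the controls and 5.30 to 8.53% in the irradiated libraries.

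Ribosomal protein genes were low in every library. The 76 genes of cytosolic ribosomal proteins had a median of 3.78 FPKM, and the highest was at 14.7 FPKM, while Fau and Rack1, components of the same ribosome whose names lack the word ribosomal, were at 373 and 268 FPKM. The 78 mitochondrial ribosomal protein genes had a median of 0.444 FPKM. No comparison between groups is given for these genes. Gene groups and full names here come from general knowledge, and the groups were chosen after the first of these low values were seen.

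**Figure D3:**
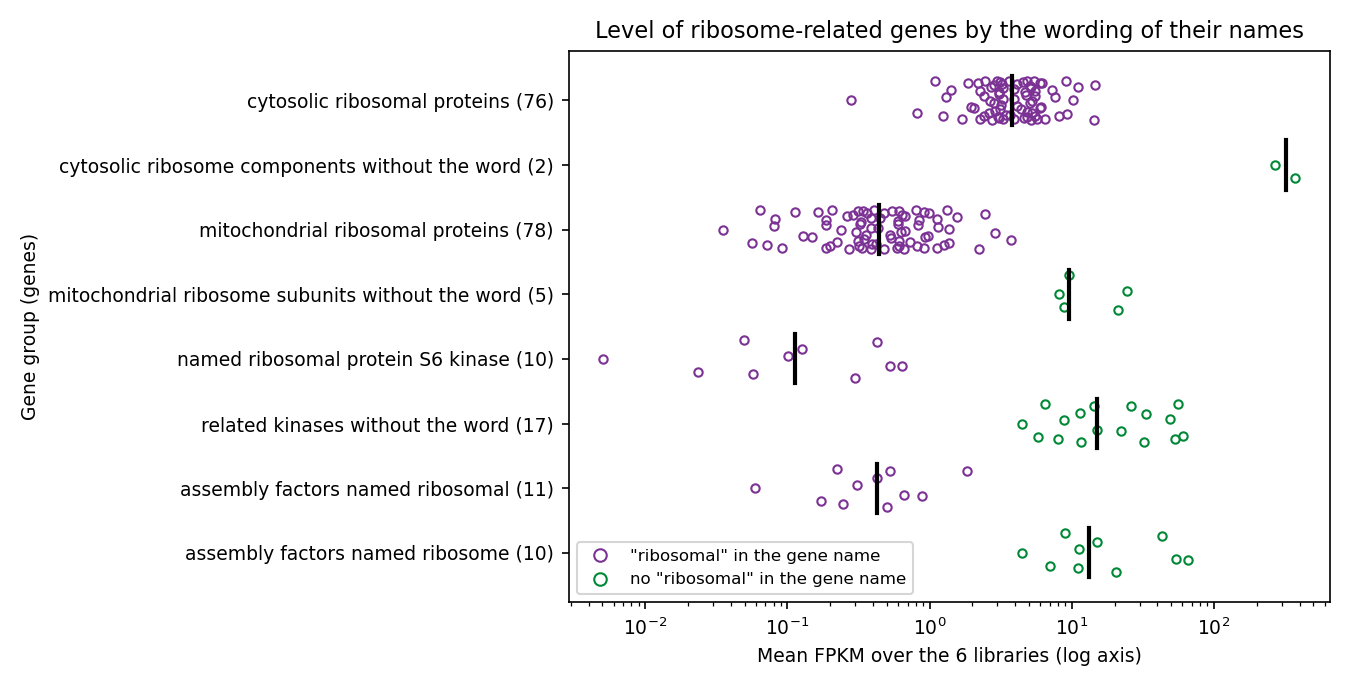
Mean FPKM over the 6 libraries on a log axis of genes related to the ribosome, grouped by whether the full gene name holds the word ribosomal (purple) or not (green); each point is a gene and the bar is the group median. Each group with the word has a median below 4 FPKM, and its partner without the word has a median of 9.54 FPKM or more.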

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

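The tests and comparisons in this part were chosen after the data had been seen. Each library's table also holds genes assembled from its reads without a name, which the comparisons above do not use. Most overlap a reference gene, and 5.39 to 7.86% of them per library overlap none. Joined across libraries, 168 such loci were present in all 6 libraries with a mean of at least 1 FPKM. In 20 of them (11.9%) the 3 irradiated libraries lay above the 3 controls, and in 20 (11.9%) they lay below, where chance gives 5% per direction. The 24.5% of tested reference genes whose groups lay apart (3413 of 13908) compare with 10% by chance for both directions together. These chance shares are expectations, and as genes vary together the share under a random grouping can lie far from them. Other splits of the 6 libraries gave 90 to 1315 genes at an unadjusted limma p under 0.05, against 2466 for the real split. Each of those splits mixes control and irradiated libraries in both groups. An effect of irradiation would widen the spread within their groups, so their counts do not show what a random grouping gives without an effect.

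The locus with the largest ratio of means among the 20 higher ones lies on chromosome 8 at 122561298 to 122567904 on the plus strand, 4976 bases from Klhdc4, and was at 6.70 ± 2.78 FPKM in controls and 27.1 ± 5.90 FPKM after irradiation. A shorter locus beside it, at 122559838 to 122560985, was at 1.33 ± 0.421 against 4.94 ± 0.599 FPKM. A more abundant locus on chromosome 2 at 75468300 to 75475046, with Hnrnpa3 as its nearest expressed gene, was at 24.3 ± 0.413 against 57.9 ± 12.9 FPKM. FPKM of assembled loci depend on the length assembled in each library, and what is annotated at these positions was not analysed here.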

How the results depend on the processing

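Rescaling to a common sum, array weights, leaving out control 2 and irradiated 2 together, and an adjusted p under 0.1 were chosen after seeing the data. The 25 called genes had the same direction of change in each alternative that tested them. The groups did not overlap for any of these genes, so leaving out libraries or changing the filter, pseudocount or variance estimate could not reverse it. The shared direction is therefore little evidence of robustness. The number of genes called, higher and lower, was 12, 5 and 7 with median-ratio scaling, 14, 8 and 6 with rescaling to a common sum, 38, 14 and 24 with a minimum of 5 FPKM (9116 genes tested), 71, 32 and 39 with array weights, 9, 9 and 0 without control 2 and irradiated 2, and 343, 148 and 195 at an adjusted p under 0.1. It was 0, 0 and 0 without a filter (31967 genes tested, 3531 at an unadjusted p under 0.05) and 0, 0 and 0 when tested against a 1.5-fold change. Leaving out each library in turn gave 0 to 116 genes called, 0 to 74 higher and 0 to 68 lower; the cause was not tested. Upper-quartile scaling (27), leaving out the 20 most abundant genes (33), a pseudocount of 0.1 (24) and ordinary variance estimates (26) gave counts within 1.5 times of 25. Rescaling to a common sum moved the median log2 change of all genes from −0.03 to 0.09, and the share of higher genes among those called was 57.1% with it and 36% without it. The rescaling also lowered the weight of the 1 added before the log, and these 2 effects were not separated.

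With the replicate number as a block 0 genes were called, 0 higher and 0 lower (1623 at an unadjusted p under 0.05), and the lists called numbered 9 higher and 5 lower, as without it. Deviations of libraries with the same number correlated at −0.17, −0.54 and −0.28, and no library correlated best with its own number. With 3 libraries per group this cannot exclude that equal numbers shared a day or batch, and the labels do not say whether they are paired.

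No list was called with an estimated correlation (0 higher, 0 lower), and fry called 1 higher (p53 targets) and 0 lower. A minimum of 5 FPKM gave 5 lists higher and 3 lower: the senescence, γδ17, αβ T and red cell lists and the alveolar fibroblast list were no longer called, and the natural killer list had fewer than 3 members left. Median-ratio scaling gave 7 higher and 6 lower, without the senescence and red cell lists and with B cells lower. Rescaling to a common sum gave 6 higher and 7 lower, without the senescence, αβ T and red cell lists and with B cells and the MHC class II list lower. Leaving out control 2 and irradiated 2 gave 15 higher and 7 lower, without the senescence, aerocyte and red cell lists. The lists newly called there, in both directions, are not named here. Leaving out each library gave 6 to 12 lists higher and 5 to 7 lower. Of the 14 called lists, the p53, γδ17, IL-17 response, neutrophil, monocyte, natural killer, alveolar type 2, endothelial and mesothelial lists kept their call without each library in turn.

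Other splits of the 6 libraries into groups of 3 called up to 6 genes, against 25 for the real split. Only 1 of the 10 splits, the real one, called as many, and 10 splits are too few for a share under 0.05. The other splits also mix control and irradiated libraries in both groups, so an effect of irradiation would lower their counts. Scaling by library size alone equals the values as deposited, since FPKM are already scaled for library size. The DESeq2 and voom alternatives were not run, since they need counts. Depth limits the low genes: without counts, no bound can be set on genes listed at 0 such as Il17a.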

Other observations

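All tests in this part were chosen after the pattern they address was seen, except that the 12 glucocorticoid-induced genes tested below were listed before their own values were seen. A set of 8 genes induced by glucocorticoids or fasting was chosen because high values had been seen in irradiated lung, so its direction is no independent evidence. Among these, Fkbp5, a chaperone of the glucocorticoid receptor, was at 6.46 ± 0.670 against 43.9 ± 25.9 FPKM, Pdk4, a kinase that limits glucose oxidation, at 3.40 ± 1.87 against 14.2 ± 3.05 FPKM, Hif3a at 0.366 ± 0.0116 against 2.42 ± 0.658 FPKM and Lpin1 at 6.98 ± 0.676 against 12.3 ± 1.47 FPKM. Tsc22d3 and Ddit4 had groups that did not overlap as well, while the groups overlapped for Per1 (20.8 ± 8.79 against 35.9 ± 10.1 FPKM) and Zbtb16 (14.5 ± 7.35 against 20.5 ± 14.8 FPKM). None of the 8 passed over all genes (limma adjusted p = 0.0565 for Hif3a and 0.0793 for Fkbp5). In the clock list, Nr1d1 was at 92.1 ± 22.9 against 43.8 ± 8.10 FPKM, Dbp at 78.9 ± 20.6 against 40.2 ± 12.6 FPKM, Cry1 at 3.73 ± 0.759 against 7.48 ± 1.18 FPKM and Per2 at 10.7 ± 2.75 against 18.4 ± 1.60 FPKM.

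A candidate explanation is stronger glucocorticoid signalling in the irradiated mice. The 12 other glucocorticoid-induced genes had positive changes in 11 of 12 cases, with a median log2 change of 0.69 (fry p = 0.0271; camera p = 0.0608 with an estimated correlation). None passed over all genes, and the groups overlapped for Arl4d, Cebpd, Errfi1, Nfkbia, Sult1a1 and Txnip. Mt2 (2.07) and Angptl4 (1.96) changed most, and Nfkbia (0.24), Txnip (0.17) and Arl4d (−0.08) least. Fasting and any other inducer of these genes were not tested apart from glucocorticoids. Another candidate is a different time of day at collection. Over approximate textbook peak hours, a 24-hour wave accounted for 47.4% of the variance of the log2 changes of 13 clock genes (permutation test, 100000 permutations, p = 0.0421). The permutations shuffled the changes among genes, not the libraries, so this p-value does not measure the spread between libraries. These tests argue against neither, the hour of collection is not given in the sources used here, and an effect of irradiation itself stays open, so the pattern is a hypothesis.

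Saa3, Lcn2 and Steap4, all inducible in inflamed epithelium and also present in other cells, may have risen with a larger share of neutrophil or airway secretory RNA. With the mean of the neutrophil list as a covariate, their log2 changes were 3.63, 2.51 and 1.94, against 3.11, 2.13 and 2.05 without it. The neutrophil list median was lower in irradiated 1 than in control 3 (0.24 against 0.91 relative to the control mean), yet Saa3 was at 30.1 against 0.996 FPKM, Lcn2 at 452 against 77.0 FPKM and Steap4 at 17.9 against 3.88 FPKM in these libraries. The 15 club and secretory markers had a median log2 change of 0.19 (SD over members 0.57, highest 1.19), below the smallest of the 3 changes (2.05), and the abundant Scgb1a1 and Cbr2 had changes of −0.83 and −0.75. The smallest change over other scalings was 100.5% of that in the values as deposited. Neutrophil RNA, airway secretory RNA and scaling are therefore argued against as the whole cause, while RNA of other cell types was not tested and a higher level per cell after irradiation stays open as a hypothesis.

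The low ribosomal protein values could come from reads shared with pseudogenes, but 12 other genes with many pseudogenes, such as Gapdh and Eef1a1, had a median of 244 FPKM, which argues against it. Another candidate explanation is that sequences were removed by the word ribosomal in their names before the tables were made. Genes that carry the word without coding for a ribosomal protein were low as well. S6 kinases had a median of 0.101 FPKM against 14.96 FPKM in 17 related kinases. Assembly factors named ribosomal had a median of 0.407 FPKM against 13.2 FPKM for genes named ribosome. The latter are assembly factors except for Rrbp1 (43.3 FPKM), a ribosome-binding protein. Mitochondrial ribosomal proteins were at 0.421 FPKM against 9.54 FPKM in 5 subunits without the word. The largest adjusted p of these 3 exact two-sided rank-sum tests was 1.08e-05, with 5 genes whose low values had been noticed first left out, so removal by name stays open, and no biological explanation was tested because the values are low in both groups.

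Immunoglobulin heavy chain genes varied widely after irradiation. Ighg2c was at 5.44 ± 3.31 FPKM in controls and at 721, 20.8 and 25.2 FPKM in irradiated 1 to 3. Ighg1 was at 0.640 ± 0.434 FPKM in controls and at 62.2, 3.68 and 16.7 FPKM in irradiated 1 to 3. Neither passed (limma adjusted p = 0.280 and 0.171), and irradiated 1 was far above the other irradiated libraries for both. Cxcl13, a chemokine of lymphoid aggregates, was at 1.93 ± 0.402 against 8.86 ± 5.85 FPKM (limma adjusted p = 0.252).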
